A study of Mus musculus with 4 samples.

How the data were processed

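CTCF ChIP-seq was analysed in 4 libraries of adult male B6CASTF1/J mouse hippocampus, grouped by the biological replicate number in the labels into 2 replicates of 2 technical libraries each. Per the labels, each replicate is a pool of 7 tissue biosamples, a possible input control exists and fragments were selected by size. The control was not used here. The sample notes list which file each deposited peak list was derived from: the technical libraries of a replicate share 1 alignment, so no value exists per library. The build is mm10, per the labels. The aligner, the peak caller, their versions and the control used for each list are not given in the sources used here.

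The files used were 4 ranked lists and 4 thresholded lists of peaks deposited by the authors. Peaks were called per replicate, on pooled reads and between replicates. The between-replicate ranked list carries the signal of the peak of replicate 1 and of replicate 2 assigned to each pooled peak: 78.4% of its first input peaks were found with the same coordinates and signal in the replicate 1 ranked list and none in that of replicate 2, and 80.3% of its second input peaks in the replicate 2 list and none in that of replicate 1. The pooled-read lists compare input peak sets that match neither replicate. The peak signal is a score of the authors' peak caller whose scale is not stated, so it was used to describe, rank and filter peaks within a list. The deposited IDR score runs to 1000, with 540 at an IDR of 0.05 and 830 at 0.01. The deposited q-value and IDR columns are given as -log10, and the p-value column is empty of values. Every peak of each thresholded list was found in its ranked list.

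The thresholded between-replicate list (IDR 0.05) was the main list, on chromosomes 1 to 19 and X. It held no peaks on Y. Coordinates are 1-based. Genes, exons and TSSs came from the GENCODE M21 basic annotation on GRCm38, the assembly that mm10 names, and chromosome lengths were checked against the peak coordinates. A summit took the first class that applied among promoter (within 1 kb of a TSS), coding exon, 5' untranslated region, 3' untranslated region, other exon, intron and intergenic. Random positions were drawn 1000 times per chromosome outside assembly gaps, in equal number to the summits. Adjacent summits under 10 kb apart were counted in the same way. Overlap of lists was computed with bedtools 2.31.1 at a minimum of 1 bp.

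The motif CCASYAGRKGGC was searched on both strands within 50 bp of each summit with at most 1 mismatch, and in an equal window 1 kb away. Orientation used summits with a match on a single strand and 100000 shuffles of strands within chromosomes. Gene lists, 15 in all, were fixed before the data were examined. A member counted as occupied with a summit within 1 kb of any of its TSSs, tested by Fisher's exact test against other protein-coding genes with Benjamini-Hochberg adjustment over the lists. The test takes members as independent, which neighbouring genes may not be. The p-values of the protocadherin, Hox and receptor lists may therefore be too small. Density was the median number of summits per 100 kb of gene body with 10 kb flanks, ranked among 10000 random lists matched on gene length. Each symbol was matched to 1 gene. Of 58 listed protocadherins 57 matched the annotation, which lists no Pcdha10 and gives the symbol Pcdha11 to 2 genes, of which 1 was used. Intervals of shares are 95% exact (Clopper-Pearson) and cover counting error only. Replicate ratios are log2 of replicate 2 over replicate 1, less the median. Read depth is unknown, so no precision per peak could be derived from it.

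Named genes and peaks followed a rule fixed together with the gene lists: the 10 protein-coding genes with the strongest promoter peak, the 3 strongest and up to 2 unoccupied members (first by alphabet) of each list, the 5 strongest peaks, and the 3 largest and 3 smallest replicate ratios. Some genes that the rule names are not reported here. The Ctcf promoter was named after its value was seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with fixed seeds.

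The code was tested on simulated data. The motif search found 100% of 1000 planted windows and called 0.3% of 1000 random ones. After adjustment over the lists, the list test called none of 300 lists without effect. Lists raised to 80% occupancy were tested singly and counted at an unadjusted p under 0.05 (Fisher's exact test). This called 92.5% of 80 lists of 17 or fewer genes and 99% of 200 larger ones. The shares for raised lists may therefore overstate the power of the adjusted test used on the data. Random points gave a promoter fold of 1.02 and a spacing ratio of 1.01, and random strands gave p under 0.05 in 0 of 20 runs.

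Alternatives tried were an IDR of 0.01, each other thresholded list (each single-replicate list leaves the other replicate out), other promoter, flank, distance and mismatch limits, other backgrounds and other overlap rules. Reducing overlapping peaks to the strongest, the comprehensive annotation and placements within 1 Mb windows were added after seeing the data. Allele-specific binding in this hybrid was not analysed here, since the lists carry no allele information. Signal tracks and alignments were not used here.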

Results

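CTCF, the zinc-finger protein that binds insulators and anchors chromatin loops together with cohesin, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hippocampal tissue of adult male mice aged 2 months. The mice were B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ. The 4 libraries formed 2 biological replicates, each a pool of 7 tissue samples, with 2 technical libraries per replicate. There was no treated or untreated group, so the design allowed a description of the sites and a comparison of the replicates. Each replicate contributed 1 signal value per peak, from both of its technical libraries together. The labels give both pools the same donor entry, so whether their animals were separate is not stated. The read depth of the libraries is unknown from the files used here, and the intervals below cover counting of peaks and genes only.

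CTCF occupied 90278 sites that passed an irreproducible discovery rate (IDR) of 0.05 between the replicates. IDR compares the ranks of peaks in 2 sets and estimates the share of calls that do not recur. Replicate 1 alone gave 76610 sites, replicate 2 alone gave 78928, and the reads of both replicates pooled and split gave 70817. The larger single-replicate list was 1.03 times the smaller, and the between-replicate list was 1.27 times the pooled-read list. At an IDR of 0.01 the between-replicate list held 80744 sites. The peaks had a median width of 440 bp and a range of 110 to 1247 bp. Exactly 440 bp was the width of 37.4% of them, so the median need not measure the extent of the sites. Of the 90278 peaks, 2037 repeated the coordinates of another peak with a different summit, and 86794 peaks were left when overlapping ones were reduced to the strongest.

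The replicates ranked these sites alike. Across 204000 ranked peaks, Pearson's r of the log2 signals was 0.94 and Spearman's rho was 0.88; peaks are not independent replicates, so no p-value was computed. Among peaks past the threshold r was 0.95, and among those not past it r was 0.45. IDR is computed from these signals, so this split follows partly from the selection and is not separate evidence of agreement. The SD of the log2 ratio between replicates fell from 0.83 in the weakest decile of peaks to 0.08 in the strongest. Past the threshold were 2.86% of the weakest decile, 1.26% of decile 3, 42.9% of decile 6 and nearly all of the strongest, 99.98%. Of the replicate 1 sites, 89.4% (95% exact interval 89.1 to 89.6) were overlapped by at least 1 bp by a replicate 2 site, and 89.3% of the replicate 2 sites by a replicate 1 site. The between-replicate list held 98.5% of the pooled-read peaks, whereas the pooled-read list held 77.7% of the between-replicate peaks. These lists share reads, so their overlaps are not independent.

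**Figure D1:**
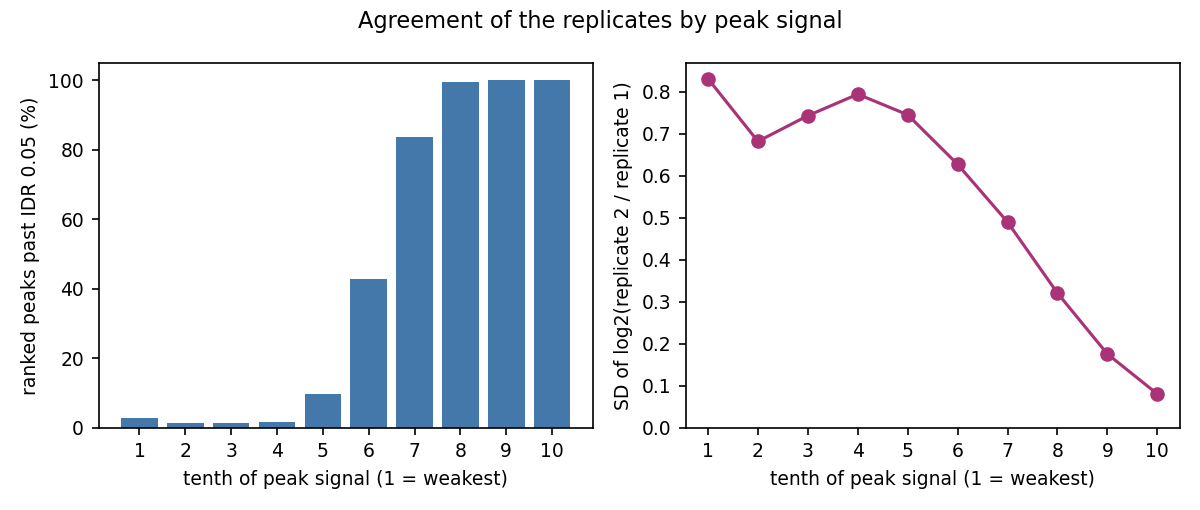
Share of ranked peaks past an IDR of 0.05 (left, percent) and SD of the log2 ratio of replicate 2 over replicate 1 signal (right) for each decile of peak signal from weakest to strongest. The share was 2.86% in the weakest decile and 99.98% in the strongest, and the SD was 0.83 and 0.08.

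CTCF sites lay at promoters far more often than chance. Summits within 1 kb of an annotated transcription start site (TSS) made up 13.9% of the list (12553 summits) against 4.52% ± 0.07 (SD) over 1000 random placements, 3.08 times as many. Introns held 48.0% of summits against 42.3% at random, coding exons 1.79% against 1.23%, and 3' untranslated regions 1.69% against 1.25%. Intergenic sequence was depleted, with 33.8% of summits against 50.05% at random. With promoters taken as 5 kb either side, the promoter fold was 1.76. Each of the differences at 1 kb gave the smallest p the placements allow in a permutation test (two-sided, p = 0.002). Of all 21755 protein-coding genes, 8268 (38.0%) had a summit within 1 kb of a TSS.

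**Figure D2:**
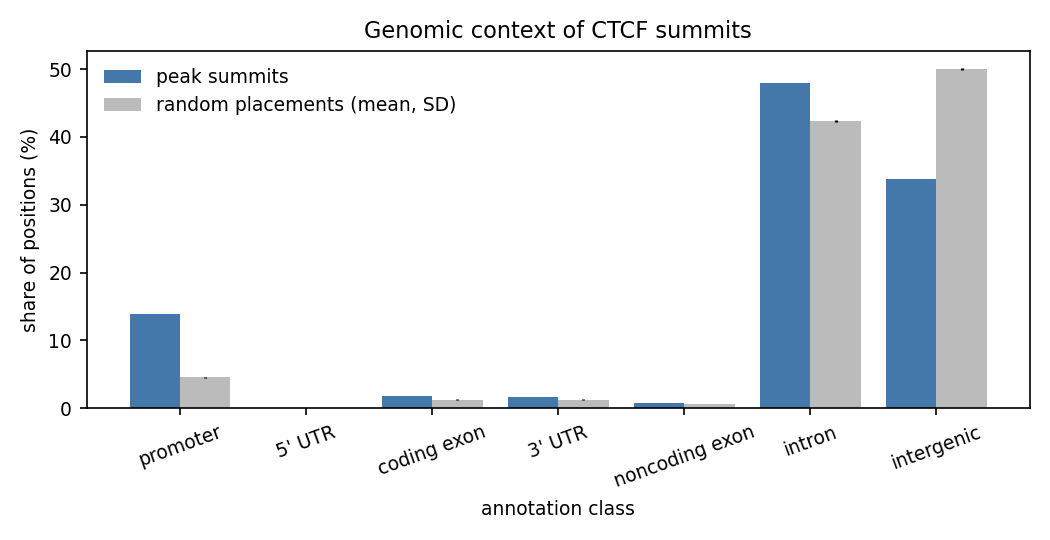
Share of CTCF summits (blue, percent) and of random positions (grey, mean and SD of 1000 placements) in each annotation class. Promoters held 13.9% of summits against 4.52% at random, and intergenic sequence 33.8% against 50.05%.

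A close match to the CTCF recognition sequence was present at about every other site. A match to CCASYAGRKGGC with at most 1 mismatch lay within 50 bp of 45381 summits, 50.3% (95% exact interval 49.9 to 50.6), against 1.25% of equal windows 1 kb away. The motif was found only at the summit for 44792 peaks and only in the control window for 540 (two-sided exact McNemar test, log10 p = -12376). An exact match was present at 10.02% of summits against 0.0886% of control windows. With at most 2 mismatches the shares were 75.7% and 8.20%, so the share depends on the limit chosen. Stronger sites carried a match with at most 1 mismatch more often, from 29.0% of the weakest decile of peaks to 74.1% of the strongest. Promoter sites carried it least often among the large classes: 27.3% of promoter summits (26.5 to 28.0), 53.8% of intronic summits and 55.5% of intergenic summits had a match. The median signal was 162 at promoters, 151 in introns and 191 in intergenic sequence.

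**Figure D3:**
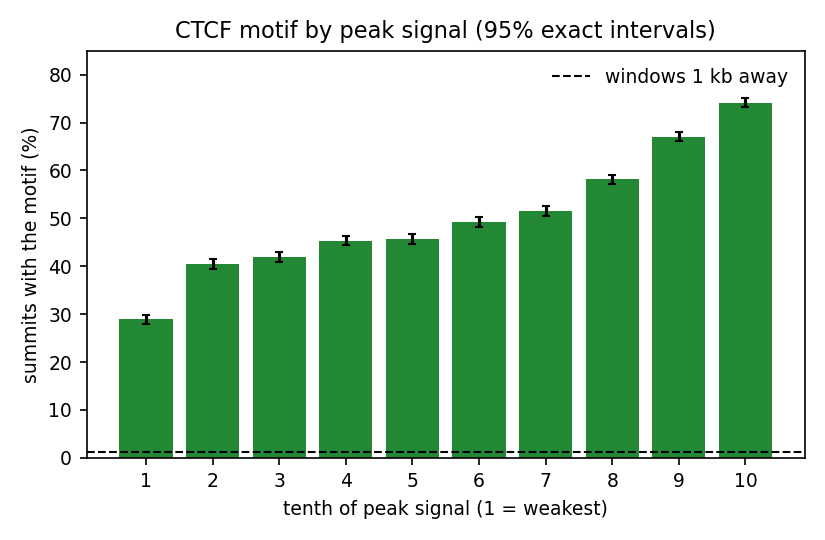
Share of summits with the CTCF motif (percent, at most 1 mismatch, within 50 bp) per decile of peak signal, with 95% exact binomial intervals; the dashed line is the share in windows 1 kb away (1.25%). The share rose from 29.0% in the weakest decile to 74.1% in the strongest.

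Neighbouring CTCF motifs faced away from each other slightly more often than toward each other. Among 42110 adjacent motif pairs under 200 kb apart, 10001 were convergent, 10300 were divergent and 21809 pointed the same way, against 21066 same-way pairs from the strand shares. The difference of -299 between convergent and divergent pairs gave the smallest p that 100000 strand shuffles allow (two-sided permutation test, p = 1e-05). Convergent pairs were spaced wider, at a median of 22817 bp against 17938 bp for divergent pairs. Convergent and divergent pairs alternate along a chromosome, so their numbers become nearly equal as the distance limit grows: under 50 kb the difference was -838 (permutation p = 1e-05, the smallest), and under 1 Mb it was -9 (permutation p = 0.33).

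The strongest sites of the genome had nearly equal signals from the 2 replicates in the between-replicate list. The highest signal, 966, was in an intron on chromosome 5 (35595667 to 35596204, mm10), where Acox3 had the nearest protein-coding TSS at 12404 bp, and an exact motif, CCAGCAGAGGGC, lay at 35595925 to 35595936. Intergenic peaks on chromosome 2 (75605615 to 75606156, nearest gene Hnrnpa3) and chromosome 13 (45030720 to 45031337, nearest gene Dtnbp1) reached 966 as well. The next 2, at 964 and 960, lay at annotated TSSs on chromosome 3 (144720192 to 144720883, Sh3glb1) and on chromosome 7 (67803433 to 67803977), the latter 43991 bp from the nearest protein-coding TSS, that of Synm. At the first of these peaks replicate 1 had a signal of 474 and replicate 2 of 500. None of the 5 had a summit within 100 bp in the pooled-read list, while 4 of 5 had one in replicate 1 alone and 3 of 5 in replicate 2 alone.

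Among protein-coding promoters, Sh3glb1, which encodes the membrane-curving protein endophilin B1, carried the strongest peak, with its summit 216 bp from the TSS. Disp3 followed with a signal of 947 (chromosome 4, 148287923 to 148288566), then Lsm11, a component of the U7 snRNP that processes histone mRNAs, with 933 (chromosome 11, 45944689 to 45945305). At Lsm11 an exact motif, CCACCAGGGGGC, lay at 45945027 to 45945038 on the plus strand. The DNA repair dioxygenase gene Alkbh2 had a peak of 929 and Wdr70 of 925. Nipsnap2 (921), Ndufc1, which encodes a subunit of respiratory complex I (920), Erlin2 (920), Ube2cbp (917) and Nudt17 (917) completed the 10 strongest. Of these 10 promoters, Sh3glb1, Disp3, Ndufc1 and Erlin2 had no match with at most 1 mismatch at the summit. Of the 10, only Disp3 had a promoter summit in the pooled-read list, and Sh3glb1, Lsm11 and Wdr70 had none in replicate 1 alone.

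Clustered protocadherins were the most occupied of the 15 lists within 1 kb of a TSS. They are neuronal cell-surface proteins whose alternative promoters are chosen with the help of CTCF. Of 57 matched members, 54 had a promoter summit, 94.7% (85.4 to 98.9) against 37.9% of other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 15 lists, p = 1.01e-18). All 11 matched alpha variable genes, both alpha C genes and all 19 gamma A and B genes were occupied, as were 21 of 22 beta genes. A single gamma C gene of 3, Pcdhgc3, was occupied. Among the alpha variable promoters 8 of 11 had 2 or more summits, and no beta or gamma promoter did. The strongest promoter peak of the group, 855, stood at Pcdhac1 (chromosome 18, 37089641 to 37090194, summit 71 bp from the TSS), followed by Pcdhgb8 (571) and Pcdhgc3 (556). Summits at 37010637 (203) and 37011320 (91.3) lay at a further annotated TSS of the alpha cluster that the list did not match, and are not among the 62. Pcdhb1 and Pcdhgc4 had no promoter summit, and Pcdhac1 had none in the pooled-read list. The region from 36910184 to 37861873 held 75 summits, 62 of them within 1 kb of a TSS of the 57 matched genes, or 7.88 per 100 kb against 3.43 over the chromosomes analysed. The median density over members exceeded that of all 10000 random lists of equal gene length. Members overlap and share summits, however, so they are not independent in this comparison or in the occupancy test.

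**Figure D4:**
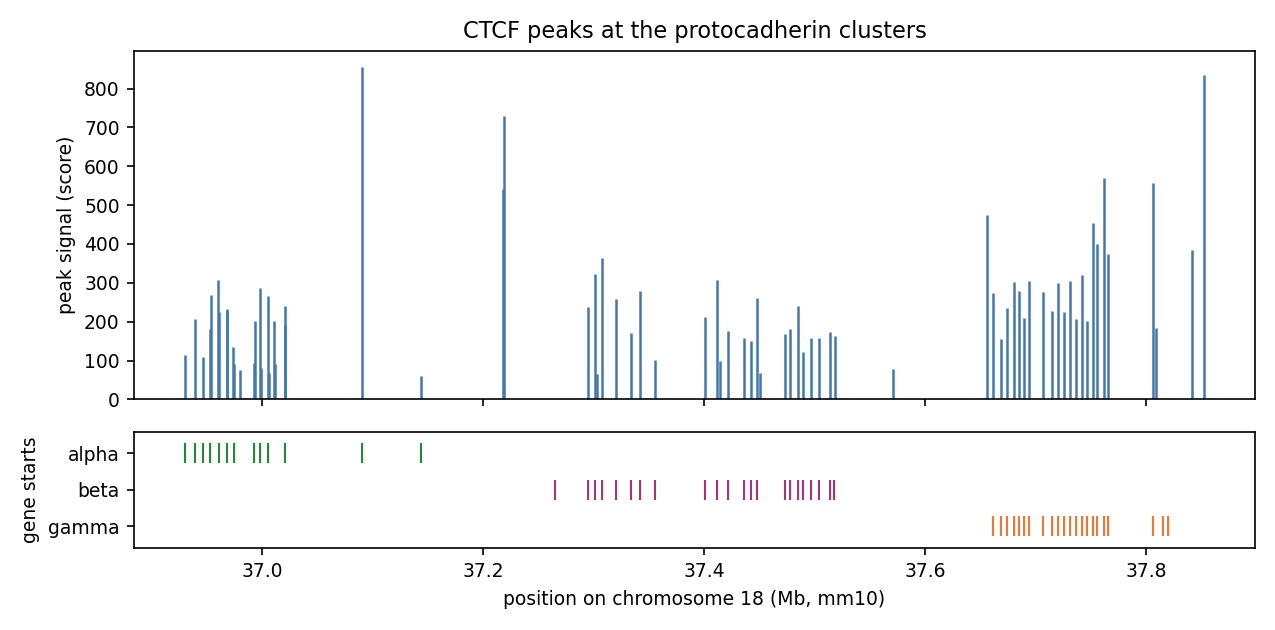
CTCF peaks at the protocadherin clusters on chromosome 18 (position in Mb, mm10): each line is a summit, its height the peak signal (score), and the ticks below mark the starts of the alpha, beta and gamma genes. Of the 75 summits 62 are within 1 kb of a TSS of the 57 matched genes and 13 are not, and the tallest, 855, is at Pcdhac1.

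Genes that neurons induce on activity were occupied more often than other genes. Promoter summits were present at 18 of 27, 66.7% (46.0 to 83.5) against 38.0% (Fisher's exact test, adjusted p = 0.017). Egr1, an immediate early transcription factor, had 3 summits with a strongest signal of 737 (chromosome 18, 34859804 to 34860340). Dusp1, a MAP kinase phosphatase, reached 706, and Bdnf, the neurotrophin with several alternative promoters, had 4 summits with a strongest of 596. Arc and Btg2 had none. Summits within 10 kb of the gene bodies were also dense, with a median of 12.8 per 100 kb against 6.19 in length-matched random lists (percentile 99.95 among random lists, adjusted permutation p = 0.006). Against random lists matched on promoter CpG content, the occupied share no longer stood apart (66.7% against 56.5%, adjusted permutation p = 0.81). Nor did it pass within 500 bp of a TSS (adjusted p = 0.076), and with 50 kb flanks the density did not pass either (adjusted permutation p = 0.76). Within 5 kb all 27 genes were occupied, 100% against 59.5% of other genes (Fisher's exact test, adjusted p = 5.4e-06). The protocadherin share within 5 kb was 94.7%. Over all alternatives the adjusted p ran from 5.4e-06 to 0.81 for occupancy and from 0.001 to 0.76 for density (exact or permutation tests).

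Olfactory and vomeronasal receptor genes, which are mostly silent outside the nose, were nearly free of promoter CTCF. Their expression was not measured here. A summit lay at 24 of 1466, 1.64% (1.05 to 2.43) against 40.6% of other genes (Fisher's exact test, adjusted p = 2.08e-269). Neighbouring receptor genes may not be independent, so this p may be too small. The strongest were at Olfr557 (761), Olfr556 (683) and Olfr15 (611), while Olfr1 and Olfr10 had none. Liver genes had a summit at 0 of 20 promoters (upper exact limit 16.8%; adjusted p = 0.000457, Fisher's exact test), among them Ahsg and Alb, which encode the plasma proteins fetuin-A and albumin. In lists matched on CpG content 11.04% were occupied, and the liver difference no longer passed (adjusted permutation p = 0.43), nor did it within 5 kb of a TSS (adjusted p = 0.08, Fisher's exact test; 0.00046 to 0.43 over all alternatives, permutation included). The receptors stayed below their matched lists (6.11%, adjusted permutation p = 0.001).

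Hox genes, which pattern the body axis and are mostly silent in forebrain, had a summit at 7 of 39 promoters, 17.9% (7.54 to 33.5) against 38.0% (Fisher's exact test, adjusted p = 0.036). Hoxc5 (644), Hoxa10 (534) and Hoxa5 (468) carried the strongest, and Hoxa11 had none. The CpG-matched share was higher, 51.4% (adjusted permutation p = 0.001). The Hox difference did not pass at an IDR of 0.01 (adjusted p = 0.085), in the pooled-read list (0.092), in replicate 1 alone (0.10) or within 500 bp (0.22), and within 5 kb it turned to 61.5% against 59.6% (adjusted p = 1, all by Fisher's exact test; 0.001 to 1 over all alternatives, permutation included).

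Genes of cohesin and other architectural factors had summits at 14 of 23 promoters, 60.9% (38.5 to 80.3), which did not pass after adjustment (Fisher's exact test, adjusted p = 0.066). It passed in the lists of replicate 1 alone (adjusted p = 0.0093), replicate 2 alone (0.024) and pooled reads (0.037), and where any base of the peak counted (0.012, all by Fisher's exact test). Against CpG-matched lists the cohesin share did not stand apart (60.9% against 55.5%, adjusted permutation p = 0.88); over all alternatives the adjusted p ran from 0.0093 to 0.88 (exact or permutation tests). Stag1, a cohesin subunit, had the strongest at 817 (chromosome 9, 100643263 to 100643853), followed by the cohesin acetyltransferase gene Esco1 (804) and Pds5a (785). The Ctcf promoter itself carried a peak of 510. Ctcfl, the testis paralogue of CTCF, and Hdac8 had no promoter summit.

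Marker genes of hippocampal cell types did not stand apart from other genes. Summits were present at 11 of 25 hippocampal subfield markers, with Pcp4 (884; none in the pooled-read list), Calb2 (804) and Map3k15 (671) strongest and none at Coch or Dsp. Of 25 excitatory and pan-neuronal genes 9 were occupied, with the NMDA receptor genes Grin2a (620) and Grin2b (571) and the neuronal splicing factor gene Rbfox3 (323) leading, and Dlg4 and Gria2 unoccupied. Interneuron markers were occupied at 5 of 22, among them Gad1, which makes GABA (649), Kcnc1 (598) and Pvalb (360), but not Calb1. Adjusted p was 0.68, 1 and 0.35 for these 3 lists (Fisher's exact test). Within 5 kb, 23 of 25 excitatory genes were occupied against 59.6% of others (Fisher's exact test, adjusted p = 0.0026; 0.0026 to 1 over all alternatives, permutation included), and the interneuron share fell below its CpG-matched lists (22.7% against 50.1%, adjusted permutation p = 0.046; 0.046 to 0.83 over all alternatives, permutation included).

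Glial and vascular markers did not stand apart from other genes after adjustment. Astrocyte markers had summits at 4 of 16 (Clu 749, Apoe 180 and Slc1a2 178; none at Aldh1l1 or Aldoc; adjusted p = 0.62, Fisher's exact test). Within 5 kb of a TSS the astrocyte share turned to 13 of 16, 81.2% against 59.6% (adjusted p = 0.21, Fisher's exact test; 0.21 to 1 over all alternatives, permutation included). Oligodendrocyte lineage markers had them at 5 of 17, with Myrf, a myelin regulator, at 803, Pdgfra at 637 and Olig2 at 354, and none at Cldn11 or Cspg4 (adjusted p = 0.71, Fisher's exact test). Microglia markers had 2 of 17, with C1qa, a complement subunit, at 257, and with Aif1 and C1qb unoccupied (adjusted p = 0.063; 0.017 with the comprehensive annotation, chosen after seeing the data; both Fisher's exact test; 0.017 to 1 over all alternatives, permutation included). Vascular markers had 3 of 14, Slc2a1 (478), Foxc1 (172) and Kdr (120), and none at Abcb1a or Acta2 (adjusted p = 0.46, Fisher's exact test).

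Imprinted genes, several of which are controlled by CTCF on 1 parental allele, had promoter summits at 21 of 48, 43.8% (29.5 to 58.8) against 38.0% (Fisher's exact test, adjusted p = 0.62). H13 had the strongest at 805 (chromosome 2, 152669137 to 152669631), with an exact motif, CCACCAGAGGGC, on the plus strand at 152669390 to 152669401. Commd1 (680) and Peg12 (651) followed, and Blcap and Cdkn1c had none. In replicate 2 alone the share was 33.3% against 33.7% of other genes, and the CpG-matched lists of the between-replicate sites had 48.4%. Within 5 kb the difference was larger, 77.1% against 59.6% (Fisher's exact test, adjusted p = 0.052). Housekeeping genes had promoter summits at 8 of 22 (Actb 814, Rplp0 780, Gpi1 255; none at B2m or Emc7; adjusted p = 1, Fisher's exact test), and the share turned above that of other genes within 5 kb (81.8% against 59.6%; adjusted p = 0.09, Fisher's exact test; 0.09 to 1 over all alternatives, permutation included). Their bodies and flanks held a median of 12.4 summits per 100 kb against 7.14 in random lists (adjusted permutation p = 0.02), which did not pass in replicate 1 alone (0.14), with 50 kb flanks (0.068) or without flanks (0.07; 0.0052 to 0.14 over all alternatives).

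**Figure D5:**
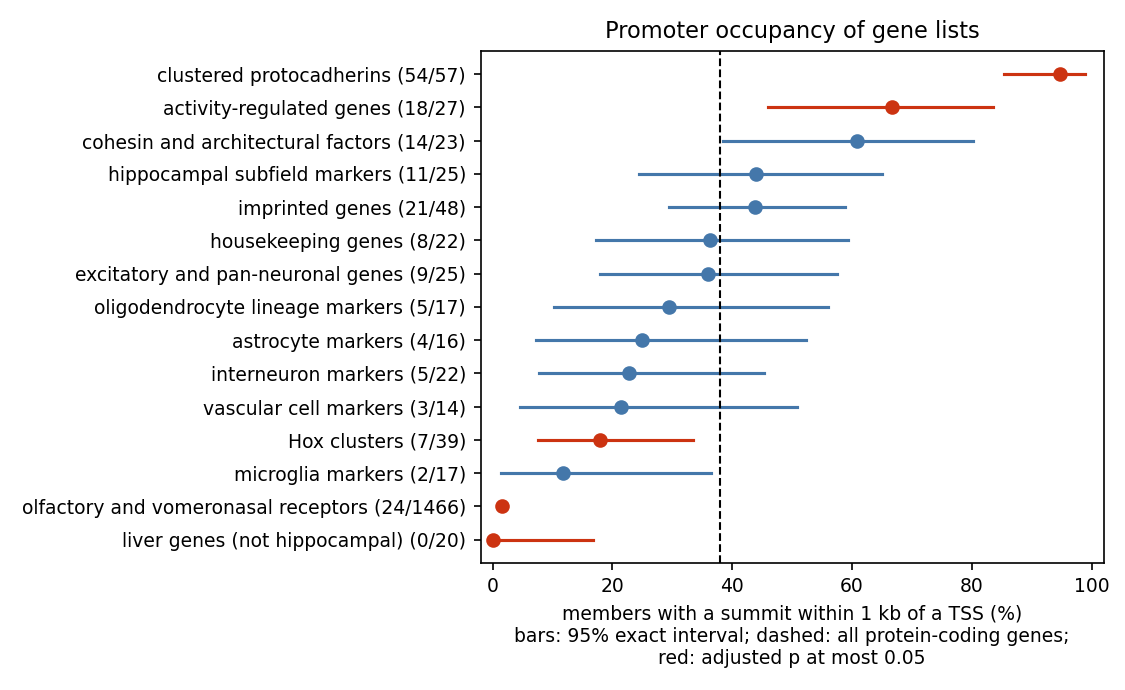
Share of each list's members with a CTCF summit within 1 kb of a TSS (percent), with 95% exact intervals and counts; the dashed line is all protein-coding genes (38.0%) and red marks an adjusted p of at most 0.05 (Fisher's exact test). Protocadherins (94.7%) and activity-regulated genes (66.7%) lie above the line, and Hox, receptor and liver genes below it.

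CTCF sites were clustered along chromosomes and sparse on X. Of adjacent summits, 48.2% were under 10 kb apart against 30.9% ± 0.12 (SD) at random, the smallest p the placements allow (one-sided permutation test, p = 0.001). Random placements that kept the number of summits in each 1 Mb window, a setting chosen after seeing the data, gave 40.7% ± 0.12 (SD; permutation p = 0.001, again the smallest). Under 50 kb the shares were 86.7% and 83.2% at random. X carried 2207 peaks, 12.9 per Mb, against 35.8 per Mb on the autosomes, a ratio of 0.361 (95% interval 0.346 to 0.376 from exact binomial limits). Among autosomes the density ran from 27.7 per Mb on chromosome 3 to 53.9 on chromosome 11. Male tissue carries 1 X per cell.

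Of the sites past the threshold, 1007 of 90278 differed over 2-fold between the pools, and 995 of these overlapped a stronger peak. IDR keeps peaks that the replicates rank alike, which limits this count. Over 2-fold from the median were 7.27% of all 204000 ranked peaks and 12.2% of those not past the threshold. Replicate 2 signals were higher by a median of 0.09 on the log2 scale, and after subtracting it the SD was 0.41 over the 90278 peaks. Over 2-fold higher were 427 peaks in replicate 2 and 580 in replicate 1. With 1 pool on each side there is no replicate check and no p-value. The largest ratios in favour of replicate 2 were on chromosome 17 (8468607 to 8469144, nearest gene T, the mesoderm regulator brachyury, 5.78), chromosome 19 in an intron (10602781 to 10603311, nearest gene Tkfc, 5.72) and chromosome 5 (140336684 to 140337195, nearest gene Nudt1, 5.48). The largest in favour of replicate 1 were on chromosome 2 at a promoter (91070284 to 91070881, nearest gene Slc39a13, -5.68), chromosome 15 (96936523 to 96937244, nearest gene Slc38a4, -5.63) and chromosome 5 (89680124 to 89680600, nearest gene Npffr2, -5.62). None of these 6 had a motif match, and at the first the peak's own signal was 18.1 while the replicate 2 signal assigned to it was 422. Reducing overlapping peaks to the strongest was a setting chosen after seeing the data. It left 12 peaks over 2-fold apart instead of 1007, and none of the 6. The SD of the ratio over the 86794 peaks left was 0.21.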

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

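The test of signal spread among the strongest peaks, the test of signal on X and the test of bound motifs on X were chosen after the result was seen. Outside the lists used above, 45 ranked peaks passed an IDR of 0.05 but were absent from the thresholded between-replicate list, so that no count or test of sites used them; the correlations and deciles of replicate agreement included them. Of these, 24 lay on other contigs and 21 on chromosomes analysed here; the cause was not tested.

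The strongest peaks were often missing from the pooled-read list: of its 1000 strongest ranked peaks 338 passed, against 996 of 1000 in the between-replicate list. False signal without CTCF would lower the motif share, which was 73.7% of 662 missing and 73.4% of 338 kept peaks. The difference was 0.343 points (95% interval -5.44 to 6.13). The interval excludes a deficit of 10 points, written beforehand as the mark of false signal. The limit of 5 points, written beforehand as the mark of its absence, is not cleared. The bound of 10 was adopted once the value was known. False signal at enough missing peaks to cost 10 points is thus argued against, while at fewer peaks it stays open. Of the missing peaks 660 had a summit within 100 bp in the between-replicate list, which shares reads, as did 336 of the kept peaks. The SD of the log2 ratio of the 2 input signals was 0.144 at missing and 0.0437 at kept peaks, 3.29 times larger (2.87 to 3.85). A larger difference between the input sets, small as both SDs are, may thus account for the loss. IDR is computed from those signals, however, so the test was nearly bound to go this way. No biological explanation was tested.

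Of the 1007 peaks over 2-fold apart between replicates, 98.8% overlapped a stronger peak of the list, against 2.78% of the other peaks. A weak peak matched to a stronger overlapping peak of 1 replicate is therefore a candidate explanation. Low signal alone stays open: after overlapping peaks were reduced to the strongest, 0% of the weakest quintile were over 2-fold apart, but the IDR threshold itself removes weak discordant peaks. No biological explanation was tested, since 1 pool stood against 1 pool.

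X had fewer peaks per Mb than the autosomes. Fewer motifs as the only cause is argued against, since a summit lay at 50.9% of exact motif matches on X and 72.5% on autosomes, a difference of -21.5 points. Fewer motifs may contribute, with 0.578 times the autosomal density of exact matches (0.526 to 0.631). Signal lowered on the single X copy may contribute as well, with a median signal of 0.654 times the autosomal one at peaks with an exact motif (0.541 to 0.766). Both values lay below the limits set for these explanations (0.6 and 0.75), but both intervals reached past them. Motifs were counted over the whole reference sequence, so the density interval treats the matches as random draws. The 2 explanations can hold together and were not told apart. Exact matches lay at only 10.02% of all summits. All samples were male, so no comparison with tissue carrying 2 X copies was possible.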

How the results depend on the processing

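Reducing overlapping peaks to the strongest, the comprehensive annotation and placements within 1 Mb windows were chosen after seeing the data. No paired analysis was possible because the groups share technical replicate numbers 1 and 2 but the peak lists carry no value per library. Of 404 values of 52 results under alternatives, 343 kept their direction and side of the threshold or their value, and 25 results did so under every alternative run. Read depth is unknown, so its limits could not be assessed. Differences for lists are in percentage points or summits per 100 kb; where values moved, the cause was not tested.

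Replicate agreement (Pearson's r) was 0.953 at an IDR of 0.05, 0.944 at 0.01, 0.881 on ranks and 0.964 with overlapping peaks reduced. The overlap of replicate 1 with replicate 2 was 83.1% with 50% of both peaks required, 86.9% with summits within 100 bp and 90.5% at an IDR of 0.01; that of between-replicate with pooled-read peaks was 77.3%, 77.0% and 82.0%, and 77.3% with overlapping peaks reduced. The rise in motif share from the weakest to the strongest decile was 43.4 points at an IDR of 0.01, 41.9 in the pooled-read list, 47.9 to 53.7 without a replicate, 36.7 with overlapping peaks reduced and 43.4 with 2 mismatches. Convergent minus divergent pairs were -9 under 1 Mb, and the fold at noncoding exons was 1.11 with 5 kb promoters. Reducing overlapping peaks left 12 peaks over 2-fold apart.

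Without either replicate, occupancy differences ranged from 27.2 to 31.2 for cohesin genes, -18.4 to -16.1 for Hox genes and -0.368 to 5.59 for imprinted genes, and the housekeeping density difference from 3.56 to 5.62. Within 500 bp, 3 lists were called; activity-regulated genes differed by 21.5, Hox genes by -12.4 and housekeeping genes by 1.48. Within 5 kb the differences were 32.4 for excitatory, 21.7 for astrocyte, 1.95 for Hox, 22.2 for housekeeping and -24.6 for liver genes. Against CpG-matched lists they were -4.67 for imprinted, -27.3 for interneuron, 10.2 for activity-regulated and -11.04 for liver genes. At an IDR of 0.01 they were -16.8 for Hox and 1.65 for housekeeping genes, and in the pooled-read list 25.4 for cohesin, -15.8 for Hox and 5.19 for housekeeping genes. With any base of the peak, cohesin genes differed by 29.6; with TSSs within 2 kb counted as 1, excitatory genes by 2.63; with the comprehensive annotation, microglia markers by -32.2 and housekeeping genes by 6.09.

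For density, 2 lists were called with 50 kb flanks and 2 with the body alone. With 50 kb flanks the differences were -1.13 for imprinted, 1.35 for activity-regulated, -0.14 for astrocyte, -0.0904 for vascular, -0.202 for cohesin, -0.211 for Hox and 3.38 for housekeeping genes. With the body alone they were -0.0271 for imprinted, -1.09 for vascular, 7.41 for housekeeping and 0 for receptor genes, and at an IDR of 0.01 cohesin genes differed by -0.312.

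Of 51 named genes with a promoter summit, 51 kept it at an IDR of 0.01, 40 in the pooled-read list, 48 without replicate 2, 51 without replicate 1 and 46 within 500 bp. The 51 were named for the strongest promoter peaks of the main list. Keeping the summit at an IDR of 0.01 was therefore likely from the selection and is no separate evidence. Of 30 without a promoter summit, 11 gained one within 5 kb.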

Other observations

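The test of motif strand at protocadherin promoters was planned before its result was seen; the account of H19 and Igf2 was chosen after their values were seen. H19, an imprinted noncoding RNA, and Igf2, the growth factor gene beside it, lie under insulator control by CTCF. Between H19 and the sequence beyond Igf2 on chromosome 7 lay 9 summits. Of these, 5 stood 1110 to 3885 bp upstream of the H19 start with signals of 145, 146, 311, 454 and 297, and 4 stood 32612, 93117, 94195 and 97726 bp upstream with signals of 688, 475, 701 and 592. At the strongest of the 5 near H19, replicate 1 had a signal of 211 and replicate 2 of 243. Which parental allele was bound was not analysed here.

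CTCF motifs at protocadherin promoters may point along transcription. With at most 2 mismatches, 5 of 9 promoter motifs, 55.6% (95% exact interval 21.2 to 86.3), lay on the strand of the gene (two-sided exact binomial p = 1), and 2033 of 3733 motifs at other promoters (54.5%) did. The interval leaves both the 80% that the hypothesis needs and the 60% that would exclude it, so the motifs were too few to decide. The planned bound called the hypothesis excluded at a share of 60% or less; the requirement that the whole interval lie below 60% was added once the value was known. Counts at other limits were 2 of 2 with 1 mismatch (exact p = 0.5) and 20 of 26 with 3 (exact p = 0.0094); the latter was 1 of 3 limits computed, not the planned one, and has no adjustment for that.

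Summits fell in softmasked repeats at 30.2%. The softmasked share of each chromosome outside assembly gaps, weighted by its number of summits, was 33.7%.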
